A study of Mus musculus with 4 samples.

How the data were processed

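The deposited table holds log2 expression values, made by the authors with RMA per the submitters' processing notes. RMA corrects the background of each array, makes the distributions of all arrays equal by quantile normalization and summarises the probes of each probe set on the log2 scale. Which software and version ran it, and whether rows were removed before deposit, is not stated in the sources used here. Per the labels' protocols, 300 ng of total RNA per pool was made into biotin-labelled sense target for an Affymetrix whole-transcript array, and each pool combined equal amounts of RNA from 3 mice. Mice were housed for 3 weeks in cycles of 12 h light and 12 h dark. An array that measures a pool averages over its mice, so the spread between pools does not show that between animals.

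The 4 arrays were grouped by genotype as WT (2 pools) and Usp2-KO (2 pools), and no array was left out. Values ranged from 2.37 to 14.58 with similar quartiles in all arrays, and no pair of arrays was identical. Of the 28270 rows, 21780 were paired with exactly 1 gene symbol by the platform's annotation, 1617 with several, and 4873 were not listed and stayed unnamed. Gene identifiers of 21689 rows matched a gene table of the GRCm38.p6 assembly, and 0 symbols were updated. This table was used for names, for the length of genes and for their order on chromosomes (19850 genes placed, 1165 on chromosome 9). The array's files name no genome build, so no coordinates are given. For each gene the row with the highest mean over all arrays was used, which left 19934 genes, of which 996 had more than 1 row. No filter on signal was applied. The 6490 rows outside these genes were tested separately over all rows.

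Usp2-KO minus WT was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 pools against 2) with genotype as the term, and p-values were adjusted by Benjamini-Hochberg. The prior had 6.87 degrees of freedom, which with those of the arrays made 8.87. Adjusted p under 0.05 was the threshold. The series' design text says that littermates were kept in step between the pools, so pools of the same number are paired, and the fit with pool number as a block was run beside the main one. As a check, the deviations of same-numbered pools from their group means were correlated across genes, which gave -0.121. Their crossing was therefore also run.

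Gene lists (40, of which 39 had at least 5 measured members) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 39 lists. They were also run with an estimated correlation and with fry, a rotation test. Both of these rest on the 2 residual degrees of freedom of the arrays, which limits how low their p can be. Within each list, genes were also adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice made later is named as such. Usp2 is in no list. The rule named Usp2, then the 12 genes of largest rise and the 12 of largest fall past the threshold with the same sign in both littermate pairs. Where fewer passed, it was filled with genes of unadjusted p under 0.01, a mean log2 value of at least 6 and the same sign in both pairs, given as values that did not pass. Predicted and unnamed gene models were left out of this filling. In each list described, up to 4 members of the smallest p were named, and up to 6 in the clock, sodium and calcium lists, where Arntl, Per1, Cry1, the Scnn1 subunits, Trpv5, Calb1 and Pdzd3 were always named. Other genes named were chosen after their values were seen.

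The fit was tested on simulated data of the same 4 arrays and 19934 genes, with 200 changed genes in each of 20 simulations. It recovered 3.75% of genes changed by 0.25 on the log2 scale, 75.8% of those changed by 0.5 and 100% of those changed by 1 or more. With the littermate block the shares were 5.88%, 81.9% and 100%. A mean of 7 of 159 calls per simulation were false, and 19.6 of 175 with the block, a share above the threshold of 0.05. A simulated list of 25 genes shifted evenly by 0.1 was called in 100% of simulations. The simulated genes were independent, with the prior of the main fit and no difference between littermate pairs. The rates need not hold for these data, where the fit with the block had a prior of 90.6 degrees of freedom.

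The alternatives were the littermate block, an intensity trend and a robust prior in eBayes, filters on signal (above the median of all genes, or a mean log2 value of at least 6), the mean of all rows of a gene, every row on its own, repeated quantile normalization, centring on medians, an adjusted p under 0.10, and each pool left out in turn. For lists, the estimated correlation and fry were added to these. Genes beside Usp2 were counted at an unadjusted p under 0.01 in stretches of 100 consecutive measured genes and compared by Fisher's exact test. Figures were drawn with matplotlib 3.10.9.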

Results

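Gene expression was measured in whole kidney of mice that lack Usp2 (Usp2-KO) and of their wild-type (WT) littermates. Usp2 encodes a ubiquitin-specific protease, an enzyme that removes ubiquitin from other proteins. The mice were C57BL6/N males, 12 weeks old, killed at Zeitgeber time 12, which per the labels is the daily peak of Usp2 expression. Kidney RNA of 6 littermate pairs was combined into 2 pools per genotype with 3 mice in each, so that each Usp2-KO pool had a WT pool of the littermates. The data are 4 arrays with 28270 values each, on the log2 scale. Array medians lay between 7.44 and 7.46. The WT pools correlated at 0.998 and the Usp2-KO pools at 0.998 across the 19934 genes tested, and arrays of different genotype correlated between 0.997 and 0.998. These correlations are across rows of the array, which are not independent replicates. The number of arrays limits the precision of every value that follows.

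Usp2 itself was the most strongly lowered transcript of the 19934 genes tested. Its log2 value was 11.67 ± 0.06 (SD, n = 2 pools) in WT kidney and 7.63 ± 0.04 (SD, n = 2 pools) in Usp2-KO kidney. The difference was -4.04 on the log2 scale (SE 0.07, 95% confidence interval -4.21 to -3.88), or 16.5-fold lower, with an adjusted p of 2.8e-08 by limma. The littermate pools differed by -3.98 and -4.11. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333, which is the value it gave. The files hold no detection calls, and the labels do not say which exons were removed, so the remaining signal cannot be assigned to transcript or background.

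The genes that the rule named besides Usp2, those of largest change with an unadjusted p under 0.01, were of several kinds. Higher in Usp2-KO kidney were Trpv5, the calcium entry channel of the distal tubule, by 0.55 (SE 0.07, adjusted p = 0.141) and Slc8a1, a sodium-calcium exchanger, by 0.54 (SE 0.09, adjusted p = 0.286). Mpzl2, an adhesion protein of epithelia, was higher by 0.78 (SE 0.10, adjusted p = 0.141), and Il18, a cytokine, by 0.47. Metabolic enzymes among the higher genes were Hpd, of tyrosine breakdown, by 0.55, Cyp2b10, a cytochrome P450, by 0.59, and Pnpla8, a phospholipase, by 0.52. Myef2 (0.55), Ppp4r2 (0.54), Polr3e (0.68) and Rangrf (0.53) completed the higher genes together with the immunoglobulin segment Igkv10-96 (1.11, SE 0.22). Lower in Usp2-KO kidney were Slc14a2, the urea transporter of the inner medulla, by -0.47 (SE 0.07, adjusted p = 0.242) and Bdkrb2, the bradykinin B2 receptor, by -0.45 (SE 0.07, adjusted p = 0.251). Cryab, a small heat shock protein, differed by -0.54 (SE 0.07, adjusted p = 0.147), the transcriptional repressor Bcl6 by -0.90 and the carboxylesterase Ces1g by -0.49. Dgkeos (-0.46), Alg9 (-0.44), Retn (-0.42), Trappc4 (-0.39) and Hyou1 (-0.39) were the other lower genes. The immunoglobulin segment Igkv19-93 was lower by -1.12 (SE 0.12, adjusted p = 0.0797). None of these passed the adjusted threshold of 0.05 in the limma comparison of the genotypes, in which Usp2 was the 1 gene that passed. With the littermate pools as a block, all 12 higher and all 11 lower genes passed, with an adjusted p of at most 0.0181. That fit uses nearly the same spread for all genes. The rule picked these genes for a large change of the same sign in both pairs. Their passing was therefore nearly given and adds little support.

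Some of these values rest on less than the others. Bcl6 differed by -1.45 in the pool 1 littermates and by -0.36 in the pool 2 littermates, and its value was -0.40 without Usp2-KO pool 1. Retn differed by -0.69 and -0.14, and by -0.21 without that pool. The value of Ppp4r2 was 0.32 without WT pool 2, and that of Ces1g was -0.32 without Usp2-KO pool 2. In the pool 1 and pool 2 littermates, Cyp2b10 differed by 0.25 and 0.93, and Polr3e by 0.96 and 0.40. Polr3e has 2 rows on the array, with changes of 0.01 and 0.68. Rangrf has 3 rows, with changes between -0.17 and 0.53, and Igkv19-93 has 2 rows, with -1.12 and -0.04. The immunoglobulin kappa segments belong to a multigene family whose probes can be shared, and Dgkeos lies opposite another gene, so their assignment is uncertain. Mpzl2, Il18, Cryab, Trappc4 and Hyou1 lie within 100 measured genes of Usp2 on chromosome 9, and Alg9 lies on the same side at place 101.

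With the littermate pools as a block, 153 genes passed the adjusted threshold, 102 of them higher and 51 lower in Usp2-KO kidney, against 1 gene without the block. The genes named above are among the 153. That fit has 1 residual degree of freedom beside a prior of 90.6, so nearly the same spread is used for all genes, and differences between the littermate pairs weigh little. In the simulations, 19.6 of 175 calls with the block were false. At an unadjusted p under 0.05, limma without the block gave 1815 genes (1041 higher, 774 lower), where 997 would be met by chance. The 2 groups did not overlap for 7754 genes, 38.9% of those tested, against 33.3% by chance.

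**Figure D1:**
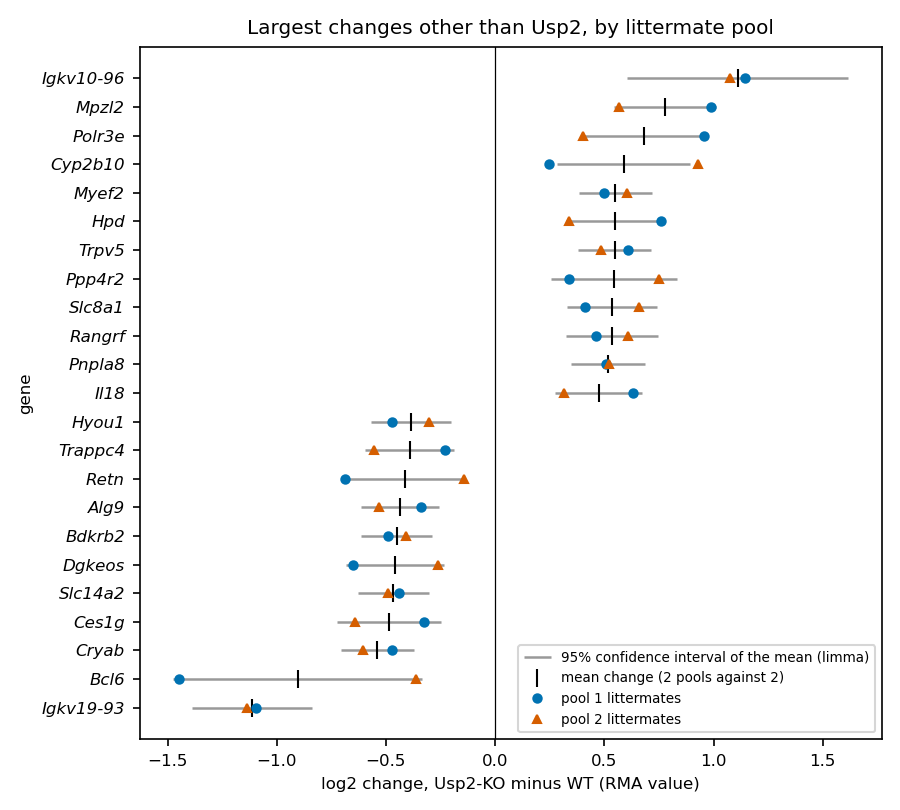
Log2 change, Usp2-KO minus WT (horizontal axis), of the 12 higher and 11 lower genes that the rule named besides Usp2 (vertical axis). Circles are the pool 1 littermates, triangles the pool 2 littermates, ticks the mean over 2 pools against 2, and bars the 95% confidence interval of the limma fit. Trpv5 lies at 0.61 and 0.49 in the 2 littermate comparisons, while Bcl6 lies at -1.45 and -0.36.

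Of the 25 measured genes of calcium, phosphate and magnesium transport, 16 were higher and 9 lower in Usp2-KO kidney, and 4 passed when adjusted over the list alone, against 0 when adjusted over all genes. These 4 were Trpv5, the apical entry channel (9.63 ± 0.02 in WT and 10.18 ± 0.06 in Usp2-KO kidney, SD, n = 2 pools), Slc8a1, the basolateral exchanger (9.53 ± 0.00 and 10.06 ± 0.18), and the cytosolic calcium carriers Calb1, which was higher by 0.44, and S100g, which was higher by 0.42. Their p-values adjusted over the list alone were 0.00101, 0.0033, 0.00499 and 0.00499 in that order. Of the other members by the smallest p, Cldn14 differed by -0.27 and Atp2b1, a calcium pump, by 0.21, and neither passed. Across the alternatives that kept this test, 4 to 8 members passed over the list alone, and Trpv5, Slc8a1, Calb1 and S100g were among them each time. With the littermate block 6 passed, with Cldn14 and Trpm7, a magnesium channel (0.05 and 0.51 in the littermate comparisons), added at an adjusted p of 0.022 each. With an intensity trend 8 passed, with Cldn14, Atp2b1, Kl and Pdzd3 added. Cldn14 also passed without WT pool 2, and it was at -0.15 without WT pool 1. Atp2b1 and Trpm7 passed without Usp2-KO pool 1, and Atp2b1 was at 0.12 without Usp2-KO pool 2. Pdzd3, a scaffold protein that lies near Usp2 on chromosome 9, differed by -0.20. The phosphate transporters Slc34a1 and Slc34a3 differed by 0.02 and -0.10.

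Camera with a preset correlation of 0.01 called the list higher relative to other genes, with a median of 0.07 and an adjusted p of 0.0133. The adjusted p was 0.676 with an estimated correlation and 0.0809 with fry, which tests against no change. It was 0.121 by camera with the trend with gene length and signal removed, a setting chosen after the data were seen. Without Trpv5, Slc8a1, Calb1 and S100g, the remaining 21 genes had a median of 0.02 and an unadjusted camera p of 0.253, a comparison chosen after the values were seen.

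**Figure D2:**
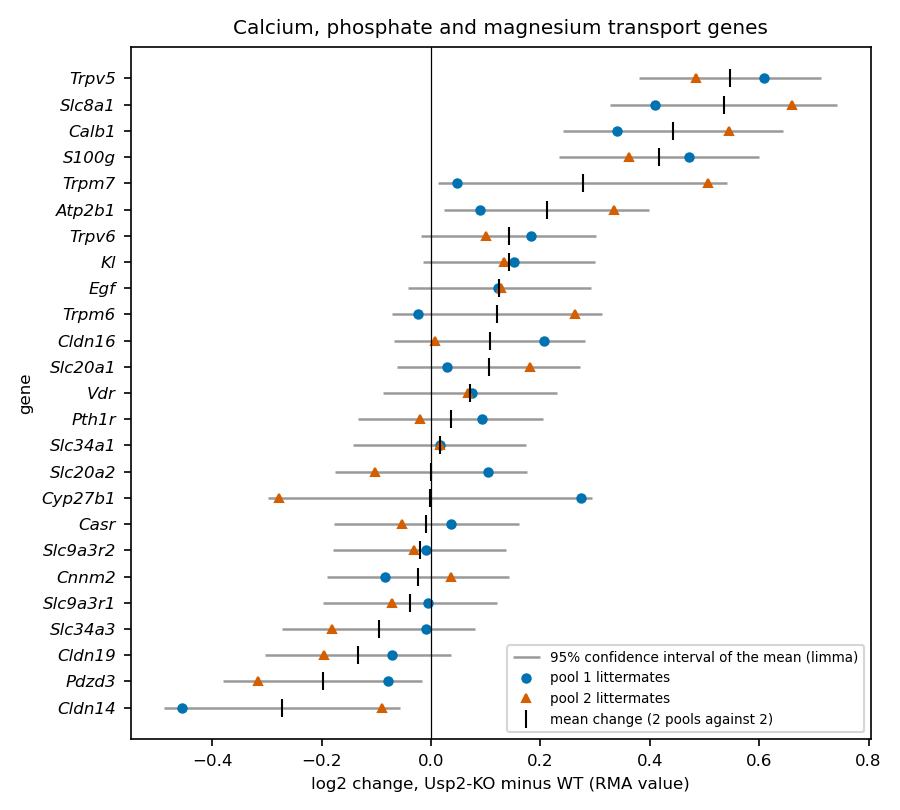
Log2 change, Usp2-KO minus WT (horizontal axis), of the 25 measured genes of calcium, phosphate and magnesium transport (vertical axis). Circles and triangles are the littermate comparisons of pools 1 and 2, ticks the mean and bars the 95% confidence interval of the limma fit. Trpv5, Slc8a1, Calb1 and S100g lie between 0.34 and 0.66 in both comparisons, and Cldn14 has the lowest mean at -0.27.

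Markers of the acid-secreting and base-secreting intercalated cells of the collecting duct were, as a list, higher relative to other genes in Usp2-KO kidney. Of 15 measured markers 12 were higher, with a median of 0.09 (camera adjusted p = 0.00426, and adjusted p = 0.676 with an estimated correlation). Fry gave an adjusted p of 0.167. Atp6v0d2, a subunit of the proton pump, was higher by 0.35 (SE 0.07) and Slc26a4, the chloride-bicarbonate exchanger pendrin, by 0.30 (SE 0.08). Both passed when adjusted over the list alone, with p of 0.0137 and 0.028. Atp6v1g3 (0.25) and Spink8 (0.24) did not, though with the littermate block both had an adjusted p of 0.0409 over the list. Without Usp2-KO pool 2 they were at 0.16 and 0.14.

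The 8 markers of the distal convoluted and connecting tubule also passed as a list (median 0.05, camera adjusted p = 0.044, adjusted p = 0.676 with an estimated correlation and 0.167 with fry), with 4 higher and 4 lower. The 3 members that passed over the list alone were Trpv5, Slc8a1 and Calb1, which the calcium list also holds. Emx1, a transcription factor, differed by -0.12, and by -0.05 without Usp2-KO pool 2 and -0.20 without Usp2-KO pool 1. The list's call was lost without WT pool 2 (adjusted p = 0.0932) and without Usp2-KO pool 2 (adjusted p = 0.107). Principal cell markers had a median of 0.05 over 12 genes (camera adjusted p = 0.242), and Aqp3, a basolateral water channel, differed by 0.19. Neither the proximal tubule list (28 genes, median 0.02, adjusted p = 0.415) nor that of the thick ascending limb (12 genes, median 0.03, adjusted p = 0.651) passed. Podocyte markers had an adjusted p of 0.198 and endothelial markers of 0.321, which was 0.0436, as lower, without Usp2-KO pool 1 and 0.862 with an estimated correlation.

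Genes of sodium transport and aldosterone response passed as a list, with 19 of 26 higher, a median of 0.04 and a camera adjusted p of 0.0466. Fry gave an adjusted p of 0.251. The call was lost with an estimated correlation (adjusted p = 0.676), with the littermate block (adjusted p = 0.0509) and when any of the 4 pools was left out (adjusted p between 0.063 and 0.155). Cul3, the ubiquitin ligase scaffold that controls WNK kinases, was higher by 0.42 (SE 0.09) and was the 1 gene that passed over the list alone (limma adjusted p = 0.0244). The subunits of the epithelial sodium channel, the aldosterone-regulated channel of the collecting duct, differed by 0.18 for Scnn1g, 0.14 for Scnn1b and 0.05 for Scnn1a, and none passed. Scnn1b was at 0.08 without Usp2-KO pool 1 and Scnn1a at 0.02 without Usp2-KO pool 2. The mineralocorticoid receptor gene Nr3c2 differed by 0.17, the kinase gene Oxsr1 by 0.17 (0.11 without WT pool 1) and Slc12a1 by 0.13 (0.07 without WT pool 2).

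Water and urea handling did not pass as a list of 13 genes (median 0.05, adjusted p = 0.414), while Slc14a2 was lower by -0.47 in it (limma adjusted p = 0.00162 over the list alone). The renin-angiotensin and vasoactive list had a median of 0.02 over 13 genes (adjusted p = 0.694). Bdkrb2 was the 1 member that passed over the list alone (limma adjusted p = 0.00196), and Ptgs2 differed by 0.17.

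Clock genes were examined because the kidneys were taken at the peak of Usp2 expression. The 20 core clock genes had a median of -0.02 and a mean of 0.01, and camera gave an adjusted p of 0.816. Rora differed by 0.24, Nfil3 by 0.30, Clock by 0.30, Arntl by -0.25, Nr1d1 by -0.19 and Dbp by -0.09. Per1 differed by -0.10 and Cry1 by 0.03. No core clock gene passed over the list alone or over all genes, but with the littermate block Nfil3 and Clock each had an adjusted p of 0.0261 over the list alone. Without WT pool 2, Nfil3 was at 0.17, Nr1d1 at -0.05, Dbp at 0.03, Per1 at 0.08 and Cry1 at -0.01. Arntl differed by -0.48 in the pool 1 littermates and by -0.03 in the pool 2 littermates, and Clock by 0.03 and 0.57. The 11 clock output genes had a median of 0.09 and an adjusted p of 0.0775, which became 0.0481 with the littermate block and 0.685 with an estimated correlation. Fkbp5 (0.28) passed over that list alone with the block (adjusted p = 0.0426), with an SD of 0.15 between the WT pools and 0.24 between the Usp2-KO pools.

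Other ubiquitin-specific proteases were, as a list, higher relative to other genes by camera, while fry gave an adjusted p of 0.167. The list of 41 measured genes also holds Usp6nl, which is not itself such a protease. Of the 41 genes 28 were higher, with a median of 0.07 and a camera adjusted p of 0.00767. The adjusted p was 0.676 with an estimated correlation. Usp1 was higher by 0.39 (SE 0.07) and Usp15 by 0.32 (SE 0.08), and both passed over the list alone with p of 0.0155 and 0.0475. Usp16 (0.27) and Usp8 (0.25) did not pass, though with the littermate block Usp16 had an adjusted p of 0.0445 over the list and Usp34 (0.29) one of 0.0419. The log2 change of all genes rose with the length of the gene in the genome (Spearman rho 0.19 across genes, which are not independent replicates), and the list's median gene stood at percentile 79.2 of that length. Targets of p53, a protein whose regulators include ubiquitin proteases, did not pass as a list (adjusted p = 0.906), and Phlda3 was lower by -0.31 (limma adjusted p = 0.0268 over the list alone).

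The remaining lists that camera called higher relative to other genes were of lipid and hormone-regulated genes. Fry gave adjusted p-values of 0.62 for cholesterol synthesis, 0.68 for fatty acid oxidation and 0.63 for androgen-regulated genes, and in the main fit 0 of their members passed over the list alone. Cholesterol synthesis genes were higher in 12 of 15, with a median of 0.06 (camera adjusted p = 0.044, and adjusted p = 0.685 with an estimated correlation). Examples were Msmo1 (0.28), Sqle (0.22), Idi1 (0.21) and Cyp51 (0.17), none of which passed over the list alone. Without WT pool 2 the value of Msmo1 was 0.10 and that of Idi1 was 0.06, and Sqle had 0.13 without Usp2-KO pool 1. All 12 androgen-regulated kidney genes were higher, with a median of 0.06 (camera adjusted p = 0.044, and adjusted p = 0.78 with an estimated correlation). Slco1a1 differed by 0.02 and 0.59 in the littermate comparisons and passed over the list alone with the block (adjusted p = 0.0292). The androgen list had an adjusted p of 0.821 without WT pool 2, 0.16 without Usp2-KO pool 1 and 0.107 without Usp2-KO pool 2. Genes of fatty acid oxidation were higher in 15 of 18, with a median of 0.07 (camera adjusted p = 0.044, and adjusted p = 0.802 with an estimated correlation). Acaa1b differed by 0.18, Pdk4 by 0.16, Acadl by 0.14 and Acot1 by 0.13, and without Usp2-KO pool 1 these values were 0.04, 0.08, 0.06 and 0.04. The fatty acid list had a mean of -0.02 without Usp2-KO pool 1, against 0.07 with all pools, and an adjusted p of 0.211 without WT pool 1. Cholesterol synthesis was not called without WT pool 2 (adjusted p = 0.204) or without Usp2-KO pool 1 (adjusted p = 0.412), nor with the mean of all rows of a gene (adjusted p = 0.052).

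Lists that camera called lower relative to other genes held markers of neighbouring tissues and early response genes. Fry gave adjusted p-values of 0.0809 for pancreatic, 0.63 for adipocyte and 0.63 for immediate early genes, and in the main fit 0 of their members passed over the list alone. All 9 pancreatic enzyme genes were lower, with a median of -0.07 and a mean WT level of 6.75 (camera adjusted p = 0.0177, and adjusted p = 0.676 with an estimated correlation). Cela3b differed by -0.21 and Ctrb1 by -0.20. Adipocyte genes were lower in 9 of 12, with a median of -0.14 (camera adjusted p = 0.0301, and adjusted p = 0.685 with an estimated correlation). Adipoq, the fat hormone adiponectin, differed by -0.83 in the pool 1 littermates and by -0.12 in the pool 2 littermates. With the block, Adipoq (adjusted p = 9.79e-05), Retn (0.00028), Cidec (0.00028), Plin1 (0.00289) and Cidea (0.00674) passed over the list alone, where Cidec differed by -0.80 and -0.04 and Plin1 by -0.65 and -0.02 in the littermate comparisons. The adipocyte list had an adjusted p of 0.417 without Usp2-KO pool 1 and 0.0932 without WT pool 2. Pancreatic genes had 0.0779 without Usp2-KO pool 1 and 0.0586 without WT pool 1. Immediate early genes were lower in 13 of 18, with a median of -0.06 (camera adjusted p = 0.044, and adjusted p = 0.685 with an estimated correlation). Klf4 differed by -0.31, Junb by -0.22, Egr2 by -0.20 (-0.10 without Usp2-KO pool 1) and Fos by -0.16. Klf4 passed over the list alone with the block (adjusted p = 0.0216). The early response list had an adjusted p of 0.518 without WT pool 2 and 0.318 without Usp2-KO pool 2. Adrenal and skeletal muscle markers each had an adjusted p of 0.0686, with medians of -0.07. Hepatocyte markers (median -0.12) had an adjusted p of 0.14, which became 0.0366 with the littermate block, and urothelial markers (median -0.14) had 0.129, which became 0.0465. Over these lists alone the block added Alb (-0.47), Apoc3 (0.26), Krt15 (-0.26) and Upk1a. In the littermate comparisons Alb differed by -0.78 and -0.16, and Upk1a by 0.09 and -0.62. With an estimated correlation the adjusted p was 0.715 for each list. Without WT pool 2 it was 0.0158 for hepatocyte markers, and without WT pool 1 it was 0.015 for urothelial markers. Hepatocyte markers had 0.0282 when the 100 measured genes on each side of Usp2 were left out, a setting chosen after the data were seen.

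Of the 39 lists tested, camera thus called 8 higher and 3 lower, relative to other genes. With an estimated correlation 0 were called, and with fry's test of 1 common direction 0 were called. Both rest on 2 residual degrees of freedom, so a call lost with them does not by itself show that correlation between genes made it. The estimated correlation was 0.81 for fatty acid oxidation and 0.63 for androgen-regulated genes. It was 0.16 for adipocyte, 0.14 for cholesterol synthesis and 0.14 for immediate early genes. For these lists, correlation between members and the few degrees of freedom cannot be told apart as the source of the lost call. The other called lists had estimates below 0.01. For the intercalated cell list the estimated correlation was 0.0045, below the preset 0.01. Its unadjusted camera p still went from 0.000109 to 0.057. With the trend with gene length and signal removed, the intercalated cell list alone passed (adjusted p = 0.0318). When quantile normalization was repeated over the tested genes, the intercalated cell list was the 1 that passed, with an adjusted p of 0.0467. Among genes with a mean log2 value of at least 6, 6 lists passed, and sodium transport, distal tubule, cholesterol synthesis, fatty acid oxidation and androgen-regulated genes did not. The stress and immune lists did not pass with all pools and genes. Heat shock genes had an adjusted p of 0.129 (median 0.08), and 0.792 with an estimated correlation. They passed as higher without WT pool 1 (adjusted p = 0.015), without Usp2-KO pool 1 (adjusted p = 0.0436) and without the genes beside Usp2 (adjusted p = 0.027), which include Cryab. The unfolded protein and ATF4 response had an adjusted p of 0.87, and the interferon response had 0.837. Adjusted p-values were 0.214 for NF-kB targets, 0.651 for macrophage, 0.473 for lymphocyte and 0.273 for class II histocompatibility genes. Within these, Cryab (-0.54), Hyou1 (-0.39) and the lymphocyte cytokine gene Ltb (-0.36) passed over their lists alone. The remaining uncalled lists, of tubule injury, stroma, cell cycle, fatty acid synthesis, oxidative phosphorylation and antioxidant genes, had adjusted p-values from 0.095 to 0.706. Tubule injury genes, the lowest of these, had 0.0381 without WT pool 1 and 0.677 with an estimated correlation. Medians and means had opposite signs for core clock, p53 target (0.03 and -0.001) and interferon genes (-0.01 and 0.01), and camera's direction was down for the unfolded protein list, whose median was 0.02. The list of erythroid genes had 4 measured members and was not tested.

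Genes that follow Usp2 on chromosome 9 differed between the genotypes more often than genes elsewhere. Of the 100 measured genes that follow Usp2 in the direction of Hyou1, 22 had an unadjusted p under 0.01, 11 of them higher and 11 lower in Usp2-KO kidney. Outside the 2 stretches of 100 genes beside Usp2 the share was 2.45% (Fisher's exact test, two-sided p = 6.59e-15). On the opposite side of Usp2 it was 3 of 100, and 7 without Usp2-KO pool 1, 6 with the littermate block and 0 without Usp2-KO pool 2. The sides hold unlike genes, since 70 of those 100 are olfactory receptor genes and 70 had a mean log2 value under 6. On the side of Hyou1 these numbers were 0 and 10, so the plain counts do not compare like genes. Among genes with a mean of at least 6, 20 of 90 had such a p on the side of Hyou1 and 1 of 30 on the opposite side. Among these genes the differences thus lay mostly on the side of Hyou1, in a comparison made without a test. The pattern was noticed after the values were seen. None of the 17561 other stretches of 100 consecutive measured genes held as many, and the highest of them held 9. The highest changes in the stretch were those of Mpzl2 (0.78), Il18 (0.47) and Bco2 (0.40), and the lowest were those of Cryab (-0.54), Nxpe2 (-0.44) and Nxpe4 (-0.40). The list of neighbours of Usp2 fixed before the data were examined did not pass as a list moving in 1 direction (39 genes, camera adjusted p = 0.414). It was 1 of 11 lists that passed fry's test for changes in either direction (adjusted p = 0.0199), among them the intercalated cell, water and urea, antioxidant, podocyte and p53 target lists. In the list of neighbours, Hyou1, Trappc4, Ccdc84 and Treh passed over the list alone. Across the alternative settings the stretch held between 11 and 26 such genes, with 11 without WT pool 2 and 13 without WT pool 1.

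**Figure D3:**
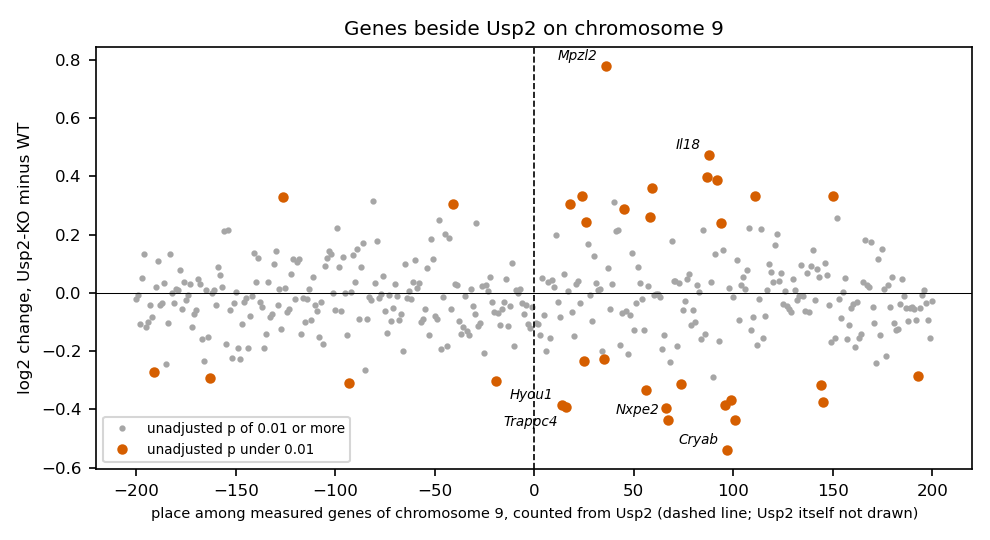
Log2 change, Usp2-KO minus WT (vertical axis), of the measured genes on each side of Usp2 on chromosome 9, in gene order counted from Usp2 at the dashed line (horizontal axis, in measured genes, Usp2 itself not drawn). Large points have an unadjusted limma p under 0.01. Within 100 genes of Usp2 there are 22 large points on the right and 3 on the left, and those on the right lie between places 14 and 99.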

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

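The crossed block, the removal of genes beside Usp2 and the removal of a trend with gene length and signal were chosen after the data were seen. Usp2 passed under all 13 alternatives, between -4.081 and -4.003. The count of genes past the threshold was 1 without a block and 153 with the littermate pools as a block, and it was 1 with the pools crossed. It was 18 with an intensity trend, 7 among genes above the median signal, 7 among genes with a mean log2 of at least 6, and 2 at an adjusted p under 0.10. Leaving out each pool in turn gave 1 to 2 genes (2 without WT pool 1 and 2 without Usp2-KO pool 2), with a lone pool assumed to vary like the others. It stayed at 1 with a robust prior, mean rows, every row, repeated quantile normalization and centring. The number of called lists, 11, became 13 with the littermate block and 13 without the 100 measured genes on each side of Usp2, and 10 with mean rows (without cholesterol synthesis). It was 0 among genes above the median signal (33 lists tested), 6 with a mean of at least 6 and 1 with repeated quantile normalization. It was 0 with an estimated correlation, 0 with fry and 1 with the trend with length and signal removed. It ranged from 6 to 11 with a pool left out. The block changed no call on a list other than those given with the results (sodium transport, clock output, hepatocyte and urothelium), and over the lists alone 20 genes were gained and 0 lost with it. A robust prior was not run for lists, since camera takes none. Signal filters test fewer genes, and the estimated correlation and fry rest on 2 residual degrees of freedom. Beyond this the cause of these shifts was not tested.

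Of 95 genes followed besides Usp2, 45 moved by over 1.5 times or turned sign with a pool left out, and 4 turned sign, each without WT pool 2. Dbp ranged from -0.213 to 0.026, Slc17a3 from -0.002 to 0.148, Per1 from -0.2835 to 0.0845 and Cry1 from -0.0125 to 0.0725. Among 19 lists, the mean or camera's direction turned as follows. Above the median signal, camera's direction turned while the mean kept its sign for core clock (0.0035) and for water and urea handling (0.0126). With repeated quantile normalization the means were -0.0118 for core clock, -2e-04 for water and urea handling and -0.009 for renin-angiotensin. With the trend with length and signal removed they were -0.0148 for core clock and -0.0115 for renin-angiotensin. With a pool left out, core clock ranged from -0.0174 to 0.0293, renin-angiotensin from -0.0295 to 0.0364, fatty acid oxidation from -0.0184 to 0.1658, proximal tubule from -0.0031 to 0.0399 and principal cell from -0.0059 to 0.0752, each lowest without Usp2-KO pool 1. None of the turned values passed its threshold. Signal over background could not be assessed, since the files hold no detection values.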

Other observations

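The tests of this part were chosen after the results were seen. The prediction for the trend with gene length and signal was an exception, written before its result. Immunoglobulin kappa variable segments moved in opposite directions, Igkv10-96 higher by 1.11 and Igkv19-93 lower by -1.12. Of the 8 such segments measured, these 2 had an unadjusted p under 0.01, and the median change was 0.05. Alas2, the heme synthesis enzyme of red cell precursors, differed by -0.38 (SE 0.10, unadjusted p = 0.00535). The other measured erythroid genes differed by 0.18 (Tspo2), 0.08 (Fech) and -0.08 (Epb42). Among the 6490 rows that name no single tested gene, 0 passed an adjusted p of 0.05 by limma and the lowest adjusted p was 0.0737.

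The stretch of genes beside Usp2 on chromosome 9 may be a segment of another strain inherited together with the targeted allele. No test here decides this, since the comparison with other stretches (0% of 17561 held as many genes of p under 0.01) restates how the stretch was noticed. An effect of the deletion that fades with distance would give the most differences nearest to Usp2, which was not seen. On the side of Hyou1, 9 genes of p under 0.01 lay in the nearer 50 places against 13 in the farther 50. The nearest of them lay at place 14. The 20 nearest genes of both sides had a mean absolute change of 0.08 against 0.13 in the next 180 (permutation test, one-sided p = 0.0252). That test cannot decide, since the 180 include the opposite side, where 70 of 100 genes had a mean log2 value under 6. Probes that bind another strain's allele less well would lower signals. In the list of 39 neighbours fixed before the data were examined, 3 genes of p under 0.01 were higher (exact binomial one-sided p = 0.0233) and 3 lower (p = 0.0051). Neither excess held each time a pool was left out, which leaves a genotype with a lone array, so this list does not decide. In the stretch itself 11 of the 100 genes were higher at a p under 0.01, against 1.56% elsewhere. Weaker binding in Usp2-KO kidney would not raise signals. But these 11 genes belong to the count by which the stretch was noticed, so their excess is no test of mismatch. For the 11 lower genes mismatch and lower expression cannot be told apart without probe sequences.

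The higher values of Trpv5, Slc8a1, Calb1 and S100g could reflect more distal tubule in the Usp2-KO pools, or regulation within the cells. More distal convoluted tubule would raise all of its markers alike. But the median over all 8 markers of the distal convoluted and connecting tubule, Trpv5, Slc8a1 and Calb1 included, was 0.048 (SD 0.29 across the markers). It lay below the 0.42 of the lowest of the 4 genes by more than that SD. Intercalated cell markers were higher with the 4 genes (mean 0.12). Principal and intercalated cell markers together had a mean of 0.08 with an upper 95% bound of 0.132 across the 27 markers. That bound holds the spread between genes, not between pools. In the littermate comparisons the means were 0.13 and 0.105 for intercalated and 0.07 and 0.002 for principal cell markers. Each of the 4 genes was at 0.34 or more in both. The marker lists thus rose less than the 4 genes. But the 4 were picked for their rise in these same data, which widens such gaps whatever the cause. Neither comparison therefore decides on a larger share of these parts of the tubule. A partial share and a larger share of connecting tubule alone were not tested, and an effect of the genotype stays open and untested. With the trend with gene length and signal removed, the changes were 0.51 for Trpv5, 0.50 for Slc8a1, 0.42 for Calb1 and 0.43 for S100g.

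The camera call on the ubiquitin-specific proteases may come in part from a trend of the log2 change with gene length and signal, as RNA quality can give. The trend explained 6.28% of the variance across genes, with a Spearman rho for length of 0.12 and 0.15 in the littermate comparisons. After its removal the list's median fell from 0.07 to 0.03 and its unadjusted camera p went from 0.000393 to 0.0449. The trend and a change of the proteases themselves cannot be told apart, because the p stayed under 0.05 while the median lost more than 50% of its size. The intercalated cell list was the 1 that passed the adjusted threshold after the removal.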
